A study of Homo sapiens with 9 samples.

How the data were processed

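PC3 cells were grown in Ham's F12 medium with serum, total RNA was taken with TRI reagent, and biotin-labelled cDNA was made with the WT PLUS kit, per the labels' protocols. The array was the Clariom S Human, with annotation release na36 on hg38, per the series design text and the annotation file's header. The deposited values are RMA expression values, per the submitters' processing notes; RMA corrects background, normalises quantiles between arrays and summarises each probe set on the log2 scale. The version of RMA and its summary level are not stated, and neither is the log base; base 2 follows from RMA. The deposited log2 values had, as the values themselves show, a constant taken off each probe set so that the median of the 3 untreated controls was exactly 0 in 21448 of 21448. That step is in no label. It leaves differences between arrays intact but removes each gene's level, so low signal could not be filtered, and how far a probe set stood above background is unknown. The transfection reagent is not given in the sources used here, nor whether the untreated controls received one.

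Of the 21448 probe sets, 18910 were given 1 current gene through the Entrez ID of the deposited annotation and a RefSeq gene table (assembly GRCh38.p14), which changed the symbol of 1083 genes. Left unnamed were 993 with several symbols, 919 with no single Entrez ID in the table, 555 with no chromosome and 71 whose RefSeq accession belonged to another gene. Gene coordinates come from the same table. One probe set stood for each of 18504 genes in the gene lists: that with a matching RefSeq accession first, then that with the lowest ID. This replaced a rule by highest mean, since the centred values hold no mean level.

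All 9 arrays were fitted in limma 3.58.1 (R 4.3.3) with a mean per group and moderated variances (lmFit and eBayes, no trend, not robust), so that the 3 groups shared 1 estimate of the spread. The 3 comparisons were contrasts of that fit, two-sided, with Benjamini-Hochberg adjustment over 21448 probe sets and a threshold of 0.05. A rise, fall or change in the text passed that threshold. Differences compare 3 arrays with 3 and are log2 differences with the fit's SE; all other errors are SD. Tables were read with Python 3.11.15 and pandas 2.3.3, and pictures drawn with matplotlib 3.10.9. The 27 gene lists were written from textbook knowledge and matched 574 memberships, of 565 genes, among the 606 symbols written. They were tested with camera (preset correlation 0.01), adjusted over the 27 lists within each comparison, with camera at an estimated correlation and with fry. Groups, comparisons, tests, lists and the rule for naming genes were chosen before the data were examined, apart from the replaced probe set rule and the alternatives named as later choices.

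The naming rule took, per comparison, the 10 largest rises and 10 largest falls among probe sets with 1 gene that passed the threshold with every array of one group beyond every array of the other. Where fewer than 10 passed, it added those with the smallest unadjusted p up to 10 in all, as not passing. BIRC5 was added in each comparison, and for each list up to 4 members with the smallest p. Every gene named by the first parts had 1 named probe set.

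On simulated arrays with each probe set's own spread, 200 of the 21448 probe sets were changed. For HpsPr-WT against control the fit recovered 44.8% of changes of log2 0.5, 92.5% of log2 1 and 100% of log2 2, with 16 false calls. For HpsPr-WC against control it recovered 41.8%, 94% and 98.5%, with 7 false calls, and for HpsPr-WT against HpsPr-WC 35.8%, 86.6% and 100%, with 10. A simulated shift of -0.3 in 1 list was called for HpsPr-WT against control (adjusted p 6.63e-29), and 0 other lists were; these simulated genes were independent of one another. A comparison with fewer true changes than the 200 simulated has a stricter adjusted threshold, so these shares do not carry over to it.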

Results

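The arrays measured steady-state transcripts in PC3, an established, androgen-independent human prostate cancer cell line. Cells were left untreated, were incubated with HpsPr-WT, or were incubated with HpsPr-WC. HpsPr-WT is a polypurine reverse Hoogsteen hairpin (PPRH), a DNA hairpin whose polypurine arm binds a polypyrimidine stretch of a gene by Watson-Crick pairing. HpsPr-WT was directed against BIRC5, the gene for survivin, and HpsPr-WC was the negative control hairpin. The sample titles call HpsPr-WC a negative control and do not name it as a PPRH. Each hairpin was given at 100 nM for 24 h. There were 3 arrays per group, titled as biological replicates, 9 in all, and each held 21448 transcript cluster probe sets. Values were on the log2 scale relative to the untreated controls, whose median was 0 in all 21448 probe sets. A gene's expression level, and so its signal over background, was not recorded, and the number of arrays limited the precision. The SD of the values over all probe sets was 0.113 to 0.163 in the control arrays, 0.207 to 0.275 in the HpsPr-WC arrays and 0.362 to 0.42 in the HpsPr-WT arrays. The control figure is lower by construction, because 1 of the 3 control values is 0 in each probe set, and cannot be set against the others. The SD of the difference between replicates of a group lay between 0.206 and 0.281.

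BIRC5 encodes survivin, an inhibitor of apoptosis protein that also belongs to the chromosomal passenger complex of mitosis. It was measured by 1 probe set (TC1700009043.hg.1; chromosome 17, 78214253 to 78225635, hg38). Its log2 values were -0.0175, 0 and 0.00125 in the control arrays, -0.46, -0.0985 and 0.103 in the HpsPr-WC arrays, and 0.0474, 0.0646 and 0.0948 in the HpsPr-WT arrays. Group means were -0.0054 ± 0.0105 (SD, n = 3), -0.152 ± 0.285 (SD, n = 3) and 0.0689 ± 0.024 (SD, n = 3). BIRC5 was thus not lower in the group given the survivin hairpin, which is written below as the arrays labelled HpsPr-WT. Every direction drawn from that group rests on its labels. Against control the BIRC5 difference was 0.07 (SE 0.124, limma adjusted p 0.715). Its 95% interval, -0.198 to 0.347, allowed a fall of at most 12.8%. That interval and adjusted p rest on the spread of all 3 groups, the widest being HpsPr-WC. A two-sided exact permutation test of the arrays labelled HpsPr-WT against control gave p = 0.1, the smallest possible with 3 arrays against 3. For HpsPr-WC against control the difference was -0.15 (95% interval -0.419 to 0.126, adjusted p 0.643, exact permutation p 0.7). Without HpsPr-WC replicate 1 that difference was 0.01. For the arrays labelled HpsPr-WT against HpsPr-WC it was 0.22 (95% interval -0.0521 to 0.493, adjusted p 0.285, exact permutation p 0.4), and 0.07 without HpsPr-WC replicate 1. The last interval allowed a fall of at most 3.55%.

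**Figure D1:**
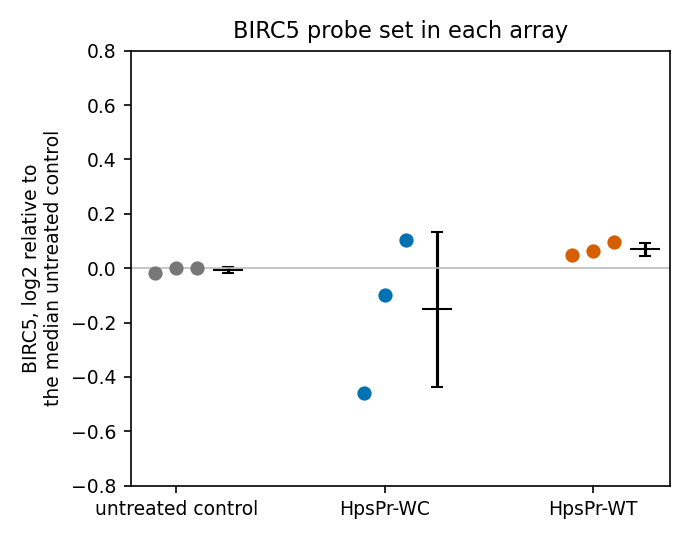
BIRC5 log2 value relative to the untreated control median (vertical axis) in each of the 9 arrays (points) by group (horizontal axis), with group means and SD. The 3 arrays labelled HpsPr-WT lay between 0.0474 and 0.0948, above the 3 controls.

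The comparison of the arrays labelled HpsPr-WT with untreated control asked which transcripts differed after the survivin hairpin, including any answer to a hairpin as such. The gene with the largest rise was APLN, which encodes the peptide hormone apelin. It stood at 4.25 ± 0.141 (SD, n = 3) against -0.0745 ± 0.307 (SD, n = 3) in control and -0.062 ± 0.26 (SD, n = 3) in HpsPr-WC arrays, a 20.1-fold difference from control (log2 4.33, SE 0.165, adjusted p 4.74e-08). RASSF1, a tumour suppressor of the Ras association family, was 16.5-fold higher (log2 4.04, SE 0.165). ACAA1, a peroxisomal thiolase of fatty acid oxidation, was 15.1-fold higher (log2 3.91, SE 0.106). TRIM15, a RING finger protein of focal adhesions, was 14.8-fold higher (log2 3.89, SE 0.155), and NKIRAS1, a small GTPase that restrains NF-kB, was 11.8-fold higher (log2 3.56, SE 0.136). The actin-binding protein gene DBN1 rose by log2 3.46 (SE 0.0983) and the endoplasmic reticulum calcium channel gene ITPR3 by 3.38 (SE 0.137). The mRNA deadenylase gene CNOT6 rose by 3.35 (SE 0.178), the microtubule-binding kinase gene DCLK1 by 3.22 (SE 0.111) and the alarmin cytokine gene IL33 by 3.17 (SE 0.102). In HpsPr-WC arrays these 10 genes had mean values from -0.149 for ITPR3 to 0.495 for CNOT6. All 10 were higher in 3 of 3 arrays than in any control.

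The falls were smaller. CBR4, a subunit of the mitochondrial fatty acid synthesis reductase, was 4.11-fold lower (log2 -2.04, SE 0.138, adjusted p 2.97e-06), the replication-dependent histone gene H2AC13 was 3.91-fold lower (log2 -1.97, SE 0.0844) and the autophagy factor gene WDR45B was 3.77-fold lower (log2 -1.91, SE 0.118). COL4A2, a basement membrane collagen, fell to -1.63 (SE 0.11), PAK1IP1, a ribosome assembly factor, to -1.60 (SE 0.136) and the homeobox gene MSX1 to -1.50 (SE 0.126). TM6SF1 fell to -1.41 (SE 0.0987), the pseudogene C22orf46P to -1.39 (SE 0.103), the long noncoding RNA CARINH to -1.35 (SE 0.0927) and the CaMKII inhibitor gene CAMK2N1 to -1.35 (SE 0.141). The largest adjusted p among these 20 genes was that of CAMK2N1, 6.03e-05. All 10 were lower in 3 of 3 arrays than in any control. In HpsPr-WC arrays the same 10 had mean values below 0, from -0.109 for WDR45B to -0.942 for CBR4, though none of these differences from control passed the test.

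**Figure D2:**
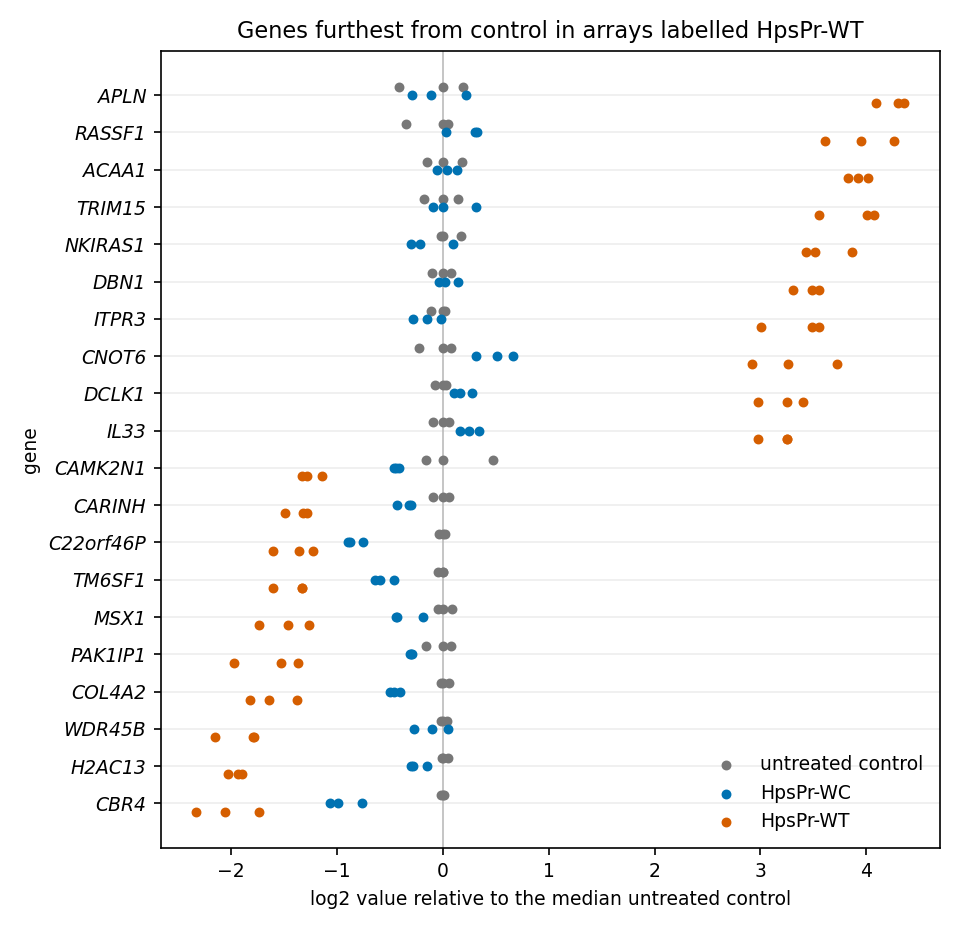
Log2 value relative to the untreated control median for the 20 genes with the largest rises and falls in the arrays labelled HpsPr-WT; points are single arrays, coloured by group. APLN stood at 4.25 and CBR4 at -2.04 in the mean of the arrays labelled HpsPr-WT, against -0.062 and -0.942 in HpsPr-WC.

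In all, 4805 of 21448 probe sets (22.4%) changed in the arrays labelled HpsPr-WT against control, 2168 higher and 2637 lower. Centring each array on its own median gave 2578 higher and 2005 lower, so that 56.3% of the calls were rises in place of 45.1%; which direction held more calls therefore depended on the scaling. Of the changed probe sets, 396 were at least 2-fold higher and 91 at least 2-fold lower, and 45 were at least 4-fold higher and 1 at least 4-fold lower. The groups did not overlap in 4730 of the 4805. Over all probe sets this held for 39%, where chance gives 10%.

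Among regulators of cell death, 5 of 23 pro-apoptotic genes rose and 1 fell against control in the arrays labelled HpsPr-WT. The BH3-only gene HRK rose by log2 0.73 (SE 0.112) and the death receptor gene FAS by 0.32 (SE 0.0903), while BAX stood at -0.48 (SE 0.107). Of 12 inhibitors of apoptosis and anti-apoptotic BCL2 family genes none rose and 2 fell, BIRC6 to -0.94 (SE 0.0951) and BIRC7 to -0.45 (SE 0.103); the remaining 10 did not pass. BCL2 stood at -0.47 (SE 0.171, adjusted p 0.0732). Of the 8 genes of the chromosomal passenger complex and its recruiters, in which survivin works, only the cohesin protector SGO1 changed, to 1.81 (SE 0.102). The complex's kinase gene AURKB stood at -0.29 (SE 0.109, adjusted p 0.0768) and did not pass.

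Among 34 genes of G2/M and mitosis 2 rose and 8 fell, and with centred arrays 3 rose and 7 fell. The cytokinesis scaffold gene ANLN rose by 1.10 (SE 0.107), while the ubiquitin-conjugating enzyme gene UBE2C stood at -0.65 (SE 0.112), the mitotic kinase gene PLK1 at -0.52 (SE 0.0932) and cyclin B1 (CCNB1) at -0.74 (SE 0.145). Among 31 genes of G1/S and DNA replication 4 rose and 3 fell, with the histone mRNA binding protein gene SLBP at 0.62 (SE 0.0982), the replicative helicase subunit gene MCM3 at 0.81 (SE 0.133) and the ribonucleotide reductase subunit gene RRM2 at -0.63 (SE 0.127). Of 24 replication-dependent histone genes in the list, which does not hold H2AC13 (-1.97), 5 rose and 1 fell: H4C8 stood at 0.96 (SE 0.146), H2AC4 at 1.19 (SE 0.195) and H4C2 at -0.55 (SE 0.0945). Of 22 p53 targets and DNA damage genes 2 rose and 3 fell, a balance that turned to 2 rises and 1 fall with centred arrays. PLK2 rose by 1.56 (SE 0.154) and TIGAR stood at -0.48 (SE 0.112).

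Stress genes went both ways. Of 26 unfolded protein response and ATF4 targets 2 rose and 3 fell, turning to 3 and 2 with centred arrays. The stress transcription factor gene DDIT3 stood at -0.87 (SE 0.0901) and ATF3 at -0.42 (SE 0.0889), and the chaperone gene DNAJB9 at 0.87 (SE 0.146). Of 13 heat shock genes none rose and 2 fell, HSPE1 at -0.45 (SE 0.0849) and DNAJB4 at -0.49 (SE 0.106). The HSP70 genes HSPA1A, HSPA1B and HSPA8 were written in that list but could not be matched, so they are not among the 13. Among 22 NRF2 and oxidative stress genes 2 rose and 1 fell, with PIR at 1.24 (SE 0.16), the cystine transporter gene SLC7A11 at 0.41 (SE 0.0906) and ferritin heavy chain (FTH1) at -0.63 (SE 0.102). Of 8 metallothioneins MT2A rose by 1.07 (SE 0.136) and MT1M fell to -0.57 (SE 0.111). Xenobiotic metabolism had 4 rises and 1 fall among 17 genes, with the cytochrome P450 genes CYP3A4 at 1.15 (SE 0.109) and CYP3A5 at 0.52 (SE 0.0969). Of 24 immediate early genes 4 rose and 2 fell: MYC stood at -0.89 (SE 0.0897), and the MAP kinase phosphatase genes DUSP5 and DUSP6 at 1.06 (SE 0.119) and 0.87 (SE 0.164).

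Genes that answer foreign nucleic acid gave no shared direction. Among 40 interferon-stimulated genes 4 rose and 5 fell, also with centred arrays, and the neighbours IFIT2 and IFIT3 went opposite ways, at 1.03 (SE 0.119) and -0.74 (SE 0.148). Of 21 nucleic acid sensors and inflammasome genes 2 rose and 4 fell, which turned to 3 and 2 with centred arrays; the cytokine gene IL18 stood at 0.60 (SE 0.111), TLR7 at 0.55 (SE 0.14) and the inflammasome adaptor gene PYCARD at -0.61 (SE 0.125). Of 30 NF-kB targets and inflammatory cytokines 4 rose and 2 fell, with IL6 at -0.61 (SE 0.106) and CXCL5 at 0.52 (SE 0.109).

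In lipid metabolism, 3 of 23 genes of cholesterol synthesis and uptake rose and none fell, and with centred arrays 4 rose. The sterol oxidase gene MSMO1 stood at 1.36 (SE 0.159), FDFT1 at 0.59 (SE 0.106) and SQLE at 0.38 (SE 0.0889). Of 12 genes of fatty acid synthesis and desaturation 2 rose and 3 fell, equal at 2 each with centred arrays; SREBF1 stood at -0.55 (SE 0.12) and ELOVL6 at 0.44 (SE 0.134). Of 28 lysosome and autophagy genes 3 rose and 3 fell, with GPNMB at 1.63 (SE 0.215), LAMP2 at 1.01 (SE 0.142) and the autophagy initiator gene BECN1 at -0.63 (SE 0.0946). Of 29 genes of glycolysis and hypoxia 2 rose and 1 fell, among them PKM at 0.49 (SE 0.113) and the glucose transporter gene SLC2A3 at -0.52 (SE 0.151). Of 28 oxidative phosphorylation genes 2 rose and 3 fell, turning to 3 and 2 with centred arrays; CYC1 stood at -0.61 (SE 0.0958) and UQCRC1 at 0.68 (SE 0.118). Of 20 cytosolic ribosomal protein genes 3 rose and 3 fell, or 3 and 2 with centred arrays. RPL19 stood at 1.27 (SE 0.142) and RPLP0 at -0.39 (SE 0.0979).

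Among 26 TGF-beta targets and mesenchymal genes 2 rose and 3 fell, or 2 and 2 with centred arrays. The matrix protein gene TGFBI stood at 1.94 (SE 0.114) and the SMAD repressor gene SKIL at 1.52 (SE 0.099), against PLAUR at -0.72 (SE 0.111). Of 17 epithelial junction genes 1 rose and 2 fell, or 1 and 1 with centred arrays. E-cadherin (CDH1) stood at 1.03 (SE 0.115) and KRT8 at -0.35 (SE 0.102). Markers of luminal prostate, fibroblasts and leukocytes each had 1 rise and 1 fall, among 13, 10 and 13 genes. These were STEAP4 at 0.31 (SE 0.0872) and KLK4 at -0.43 (SE 0.136), COL5A1 at 0.31 (SE 0.0894) and POSTN at -0.34 (SE 0.108), and CD14 at 0.71 (SE 0.172) and MS4A1 at -0.51 (SE 0.0887). With centred arrays the luminal and fibroblast lists had 1 rise and no fall.

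Across the 27 lists, 63 of 574 memberships rose and 60 fell against control in the arrays labelled HpsPr-WT, 21.4% in all. Over all probe sets 22.4% changed, so the lists together held no larger share. When adjusted over the list alone, 63 rose and 62 fell. The camera test, which asks whether a list shifts against the other genes, called 0 of 27 lists, with a smallest adjusted p of 0.503. The 1 list with an unadjusted p under 0.05 was the pro-apoptotic one (median 0.105, p 0.0186). With an estimated correlation camera also called 0 lists (smallest adjusted p 0.934). The fry test, which asks whether a list's genes move on balance one way without comparing them with other genes, called 7 lists. Down were G2/M and mitosis (median -0.142, adjusted p 0.0237), inhibitors of apoptosis (-0.233, 0.0237), leukocyte markers (-0.129, 0.00475) and the unfolded protein response (-0.0471, 0.0321). The median of the last was no lower than that of all probe sets, -0.0531, and was 0.00144 with centred arrays, so its fall did not stand apart from the arrays' offset. Up were cholesterol synthesis (median 0.00764, adjusted p 0.0118), the chromosomal passenger complex (-0.0403, 0.0114) and xenobiotic metabolism (-0.0691, 0.0321). The mean of the passenger complex list, 0.146, and that of the xenobiotic list, 0.111, differed in sign from their medians. Of the 8 passenger complex genes only SGO1 had changed, and the list was not tested without it. In its mixed form, which asks for change in either direction, fry called 27 of 27. Median, mean, camera and fry were not all of one sign in 11 of the 27 lists.

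The comparison of HpsPr-WC with untreated control asked what the negative control hairpin changed, and 1 of 21448 probe sets passed. It was RPRD1B, which encodes a protein that binds the C-terminal domain of RNA polymerase II. RPRD1B stood at -0.927 ± 0.0298 (SD, n = 3) against -0.00652 ± 0.139 (SD, n = 3) in control, a fall of log2 -0.92 (SE 0.0982, adjusted p 0.0244) seen in 3 of 3 arrays. The arrays labelled HpsPr-WT had a like value, -0.89 from control (SE 0.0982, adjusted p 9.14e-05), and RPRD1B did not differ past the test between the hairpins (0.03, adjusted p 0.903). Its adjusted p rose above the threshold without control replicate 1 (0.267), without HpsPr-WC replicate 1 (0.172), 2 (0.266) or 3 (0.0751), and without HpsPr-WT replicate 1 (0.0721). It did so too when the 6 arrays compared were fitted alone (0.0576) and with a block for the replicate number. Over all alternatives it ranged from 0.00296 to 0.267. At an unadjusted p under 0.05 there were 2665 probe sets by limma. The groups did not overlap in 17.2% of probe sets, where chance gives 10%.

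The 9 genes next in line did not pass. The pseudogene C22orf46P stood at -0.84 (SE 0.103, adjusted p 0.0514), CBR4 at -0.94 (SE 0.138) and the glutathione synthetase gene GSS at -0.95 (SE 0.143). The growth factor gene BMP7 stood at -0.68 (SE 0.103), the apolipoprotein gene APOC4 at -0.83 (SE 0.132) and the deglycosylating enzyme gene ENGASE at -0.63 (SE 0.102). Above control were the protocadherin gene PCDH18 at 0.72 (SE 0.112), the cilia gene CFAP58 at 0.70 (SE 0.111) and the anion transporter gene SLC26A7 at 0.62 (SE 0.1). The adjusted p was 0.136 for each after C22orf46P. In the arrays labelled HpsPr-WT, CFAP58, CBR4, C22orf46P, ENGASE and BMP7 stood farther from control, at 2.13, -2.04, -1.39, -1.24 and -0.70. APOC4, GSS, PCDH18 and SLC26A7 stood nearer, at -0.77, -0.69, 0.49 and 0.31. Between the hairpins BMP7, APOC4, GSS and PCDH18 did not differ past the test (limma adjusted p 0.928, 0.842, 0.277 and 0.212).

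No list membership rose or fell after HpsPr-WC. Adjusted over the list alone, 4 rose, among them IL24 at 0.47, SKIL at 0.42 and GSTP1 at 0.35, and IFIT5 fell to -0.45. The genes named here were chosen after their values were seen. Camera called 0 lists (smallest adjusted p 0.238) and had 4 with an unadjusted p under 0.05: epithelial junction genes (median -0.13) and NRF2 targets (-0.0674) lower, pro-apoptotic genes (0.0859) and fibroblast markers (0.115) higher. Camera with an estimated correlation and fry each called 0 as well, with smallest adjusted p of 0.914 and 0.525. The largest difference, PIGK at 1.46 (SE 0.295), did not pass (adjusted p 0.256).

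The comparison of the arrays labelled HpsPr-WT with HpsPr-WC asked what set the survivin hairpin apart from the control hairpin at one dose and time. The 10 genes with the largest rises were those that rose most against control. APLN was 19.9-fold higher (log2 4.32, SE 0.165, adjusted p 5.52e-08), ACAA1 14.8-fold (log2 3.88, SE 0.106) and TRIM15 13.9-fold (log2 3.80, SE 0.155), while CNOT6, at 0.495 ± 0.175 (SD, n = 3) in HpsPr-WC arrays, was 6.99-fold higher (log2 2.81, SE 0.178). The other six, NKIRAS1, RASSF1, ITPR3, DBN1, DCLK1 and IL33, lay between 13.4-fold and 7.52-fold. Among the falls, WDR45B stood at -1.80 (SE 0.118), H2AC13 at -1.71 (SE 0.0844) and PAK1IP1 at -1.32 (SE 0.136). STAC, an adaptor of calcium channels, stood at -1.51 (SE 0.104), the cAMP phosphodiesterase gene PDE7B at -1.37 (SE 0.114) and the snRNA export adaptor gene PHAX at -1.34 (SE 0.0795). CYSTM1 stood at -1.28 (SE 0.164), the kinase gene FRK at -1.26 (SE 0.119) and the metabolic coactivator gene PPARGC1A at -1.24 (SE 0.105). PIGK, a subunit of the GPI anchor transamidase, stood at -1.40 (SE 0.295, adjusted p 0.00684). Its difference lay in the HpsPr-WC arrays, at 1.6 ± 0.492 (SD, n = 3) against 0.196 ± 0.442 (SD, n = 3) in the arrays labelled HpsPr-WT and 0.143 in control. All 20 were separated in 3 of 3 arrays.

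In this comparison 3746 probe sets changed (17.5%), 1512 higher and 2234 lower, and 1788 higher and 1760 lower with each array centred on its median. The share of rises was 40.4% and 50.4%. At least 2-fold changes numbered 259 higher and 59 lower. Of the 3746, 3714 were separated between the groups; over all probe sets 32.4% were, where chance gives 10%. Of the probe sets called here, 3011 were also called against control, 3010 of them in the same direction; both comparisons use the same arrays labelled HpsPr-WT, which makes such overlap by itself.

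The lists against HpsPr-WC rest on the same 3 arrays labelled HpsPr-WT as those against control, so like counts are not independent. In G2/M and mitosis 2 rose and 8 fell, or 2 and 7 with centred arrays: ANLN stood at 0.94 (SE 0.107), UBE2C at -0.66 (SE 0.112), NUSAP1 at -0.88 (SE 0.14) and the hyaluronan receptor gene HMMR at -1.14 (SE 0.204). SGO1 was the only one of 8 passenger complex genes to change, at 1.89 (SE 0.102). Of the pro-apoptotic genes 2 rose and 1 fell, with HRK at 0.54 (SE 0.112) and BAX at -0.50 (SE 0.107), and of the inhibitors of apoptosis BIRC6 alone fell, to -0.89 (SE 0.0951). MYC stood at -0.92 (SE 0.0897) and DDIT3 at -0.77 (SE 0.0901). Of the 13 matched heat shock genes 2 fell and none rose, HSPE1 to -0.46 (SE 0.0849) and DNAJB4 to -0.44 (SE 0.106). Of the listed histones 3 rose and 1 fell, or 3 and none with centred arrays, with H1-4 at 0.91 (SE 0.131); H2AC13, at -1.71, is outside the list. In cholesterol synthesis 3 rose and 1 fell, with MSMO1 at 1.61 (SE 0.159) and FDFT1 at 0.53 (SE 0.106). TGFBI stood at 1.67 (SE 0.114), CDH1 at 0.80 (SE 0.115) and CYP3A4 at 1.10 (SE 0.109). Of the interferon-stimulated genes 1 rose and 3 fell, IFIT2 at 0.80 (SE 0.119) and IFIT3 at -0.77 (SE 0.148), or 2 and 3 with centred arrays.

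Over the 27 lists 45 of 574 memberships rose and 53 fell in this comparison, 17.1% in all, against 17.5% of all probe sets. When adjusted over the list alone, 47 rose and 57 fell. Camera called 0 lists (smallest adjusted p 0.322). Those with an unadjusted p under 0.05 were 2, heat shock lower (median -0.218, p 0.0119) and replication-dependent histones higher (median 0.045, p 0.0324). With an estimated correlation camera called 0 (smallest adjusted p 0.903). Fry called 7 lists, with leukocyte markers (median -0.112, adjusted p 0.00194), heat shock (-0.218, 0.0273) and G2/M and mitosis (-0.0618, 0.0409) down. Up were the passenger complex (median 0.0555, adjusted p 0.0024), cholesterol synthesis (-0.0106, 0.03), the listed histones, without H2AC13 (0.045, 0.0409), and xenobiotic metabolism (0.0549, 0.0493). Of the 8 passenger complex genes only SGO1 had changed. Adjusted over that list alone, 1 rose and 2 fell, and the list was not tested without SGO1. The mean of the cholesterol list was 0.0547, opposite in sign to its median. Mixed fry called 26. The signs of median, mean, camera and fry were not all one in 9 lists, against 4 for HpsPr-WC against control. The ribosomal list had 2 rises and 3 falls, which turned to 2 and 1 with centred arrays.

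The differences of both hairpins from the same controls were set side by side over 21448 probe sets, which are not independent replicates. Pearson's r was 0.462, Spearman's rho was 0.498, and 69.3% of probe sets had the same sign. Unchanged groups simulated against the shared controls (100 data sets) gave a mean r of 0.5, with a highest of 0.522, and 66.6% of the same sign. That r holds where neither group changed, and the observed r also carries the wider spread of the arrays labelled HpsPr-WT, so the covariance is the measure to compare. The covariance, 0.0315, exceeded the simulated mean of 0.00956 and maximum of 0.0102 by 0.0219 over the mean. RPRD1B was the 1 probe set lower in both, where independent lists would share 0.123, and none was higher in both, with 0 expected. The simulated groups shared their controls too, but their probe sets were drawn independently of one another. In the real arrays the first principal component held 35% of the variance of the deviations from group means. The simulated maximum may therefore be too low a bound, and no conclusion on sharing is drawn from the excess. The simulated groups held no changes, so their share of the same sign need not carry over to changed groups. With 3 control arrays a split cannot leave 2 in each part, and no uneven split was run, so the sharing was not removed. Without control replicate 3, r was 0.544.

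**Figure D3:**
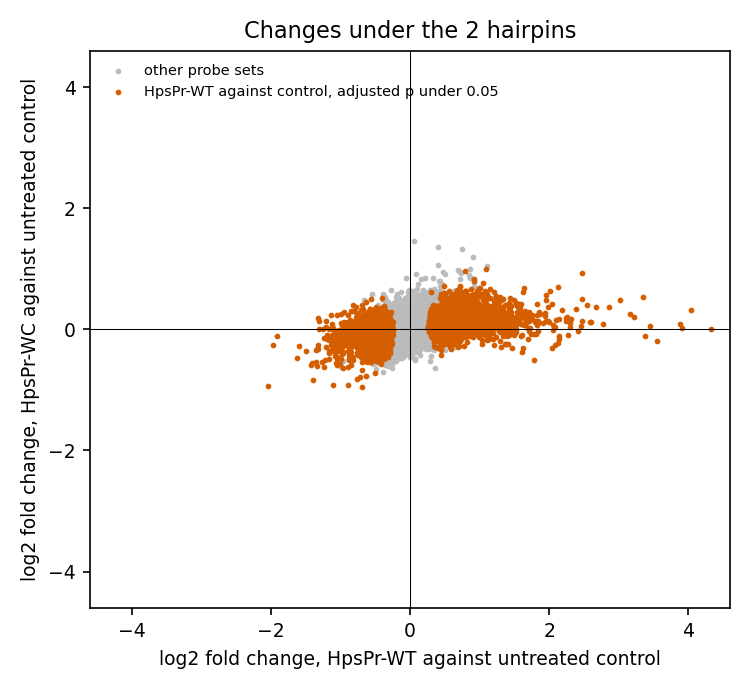
Log2 difference from untreated control in the arrays labelled HpsPr-WT (horizontal axis) against that in the HpsPr-WC arrays (vertical axis), 1 point per probe set, in orange where the former passed the test. The spread was wider for the arrays labelled HpsPr-WT, with an SD of 0.372 against 0.183.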

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

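The alternatives chosen after the data were seen were the robust fit without trend, 1 probe set per gene by RefSeq accession, the first principal component of the deviations from group means as a covariate, and taking off a running median over probe sets in the order of their numbers. For the arrays labelled HpsPr-WT against control, the count of 4805 stayed within 1.5 times under these 4, array weights (5900), the 6 arrays alone (4532), centring (4583), an adjusted p under 0.1 (6472) and each array left out in turn (3310 to 4959). With a minimum of 1.5-fold 1821 remained by construction, 1087 higher and 734 lower, and 489 had an unadjusted p under 0.05 and at least 2-fold change, 398 higher and 91 lower. For the arrays labelled HpsPr-WT against HpsPr-WC, 3746 became 1457 and 319 under the same thresholds, and the range with 1 array left out was 2599 to 3642. The share of rises moved from 45.1% to 56.3% with centred arrays and to 57.6% after the running median, and from 40.4% to 50.4% and 51.7% in the second comparison.

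For HpsPr-WC against control, where 1 probe set passed, the count was 0 with the 6 arrays alone, 50 with array weights, 2 with centred arrays, 2 with 1 probe set per gene, 46 with the principal component as covariate, 2 after the running median, 2 at an adjusted p under 0.1, and 7 at an unadjusted p under 0.05 and at least 2-fold. The component was drawn from the same deviations that the test uses as its error, so its 46 calls are not independent evidence. With 1 array left out the count ran from 0 to 8: 0 without control replicate 1, any HpsPr-WC replicate or HpsPr-WT replicate 1; 8 without control replicate 3; 3 without HpsPr-WT replicate 2; and 2 without HpsPr-WT replicate 3. Leaving out an array of a compared group also leaves fewer samples; for the rest the cause was not tested.

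The replicate numbers were not shown to pair the arrays. The deviations of arrays with the same number correlated at -0.003, 0.191 and 0.02 between HpsPr-WT and control. They correlated at 0.032, -0.013 and -0.238 between HpsPr-WC and control, and at 0.302, -0.145 and -0.168 between the hairpins. These values do not settle whether arrays of the same number were made together. With a replicate block the counts were 4499, 0 and 3468 in place of 4805, 1 and 3746, RPRD1B had an adjusted p of 0.223 in HpsPr-WC against control (0.00296 to 0.267 over the alternatives), camera called 0 lists in each comparison, and the agreement of the hairpins was 0.462 by construction, since a block in a balanced design leaves the differences as they were.

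Fry called 7, 0 and 7 lists where camera called 0, 0 and 0; the tests ask different questions. With each array left out, camera called 0 lists in each comparison. The correlation of the hairpins' differences ranged from 0.416 to 0.544, the last without control replicate 3, and the cause was not tested. BIRC5 in HpsPr-WC against control ranged from -0.2738 to 0.007859 with 1 array left out, its sign turning without HpsPr-WC replicate 1. In the arrays labelled HpsPr-WT it ranged from 0.06139 to 0.0851 against control and from 0.06646 to 0.3482 against HpsPr-WC, and its adjusted p did not pass in any setting (0.0626 to 0.992 over the 3 comparisons).

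The 20 named genes of each comparison with the arrays labelled HpsPr-WT were picked in these same arrays for large differences, which favours stability. They kept direction and side of the threshold in all 340 values from 17 alternatives. For HpsPr-WC against control 139 of 170 did, 24 passed where the gene had not, and 7 no longer passed, all of RPRD1B, whose adjusted p ranged from 0.00296 to 0.267. None of these genes turned in sign. BIRC5, not counted here, did turn in HpsPr-WC against control (-0.2738 to 0.007859). Genes named only as list members were not followed. A filter on low signal, a variance trend, renewed quantile normalisation and the Pearson correlation or camera after a filter were not run, because the centred values hold no signal level. For the same reason signal over background could not be set as a limit.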

Other observations

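The tests of probe set numbering and of exchanged labels, and the counts by chromosome and by symbol family, were chosen after the results were seen, as was the check of list members that voided the test of BIRC5 against mitosis genes.

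The share of genes that changed in the arrays labelled HpsPr-WT against control varied between chromosomes. Rises made up 16.8% of measured genes on chromosome 8 (adjusted p 1.72e-06 by Fisher's exact test), 13.8% on chromosome 9 (0.00272) and 13.3% on chromosome 17 (0.00178), against 3.42% on chromosome 22 (7.5e-06), 6.85% on chromosome 2 (0.000717) and 7.23% on chromosome 1 (7.45e-05). Falls made up 20.8% on chromosome 22 (1.82e-05) and 19.3% on chromosome 21 (0.0167), against 7.38% on chromosome 7 (4.83e-05). With each array centred on its median, rises made up 18.1% on chromosome 8 and 4.65% on chromosome 22, and falls 17.1% on chromosome 22. These tests treat genes as independent. Against HpsPr-WC chromosome 22 again had few rises, 2.2%, and many falls, 16.9%. Genes grouped by the letters of their symbols gave no family past the adjusted threshold in these comparisons (smallest adjusted p 0.938 by Fisher's exact test). The families with the smallest unadjusted p against control were KRTAP, with 18 of 89 genes lower (p 0.0327), and PDE, with 6 of 25 higher (p 0.0335).

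Genes of families whose known expression lies mostly in other tissues changed as well. Of 378 olfactory receptor genes 40 rose and 44 fell in the arrays labelled HpsPr-WT against control, a balance that turned to 47 and 27 with centred arrays, and 7 rose at least 2-fold. Keratin-associated proteins had 10 rises and 18 falls among 89 genes, beta-defensins 5 and 1 among 32, late cornified envelope proteins 3 and 3 among 18 (4 and 2 with centred arrays), bitter taste receptors 2 and 2 among 22, and vomeronasal receptors 1 and 1 among 6. The largest rises, named after their values were seen, were OR5K3 at log2 1.99 (SE 0.116), OR51F1 at 1.98 (SE 0.179) and KRTAP2-1 at 1.68 (SE 0.126).

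The first pattern weighed is the large number of probe sets that changed in the arrays labelled HpsPr-WT. If those calls reflected transcripts of the named genes, the families above, taken to be mostly silent in prostate cells, should change less often than other genes. They did not: the ratio of shares was 1.12 for rises (11.2% against 9.98%; 95% interval 0.863 to 1.41) and 1.04 for falls (12.7% against 12.2%; 0.807 to 1.28). With centred arrays the ratios were 1.08 and 0.905. Against HpsPr-WC they were 1.04 for rises (0.739 to 1.36) and 0.819 for falls (8.62% against 10.5%; 0.607 to 1.07), the falls being fewer in the families with an interval that includes 1. A ratio with its interval below 0.5 would have counted against signal from other sources. At least 2-fold rises made up 2.02% and 1.79% (Fisher's exact p 0.624). Many calls may therefore stem from signal other than the named transcript. Without levels, though, the silence of the families in PC3 could not be checked, and single members may be expressed.

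A second test took 17 genes with several probe sets of which at least 1 had risen at least 2-fold. The leading sets had a median of 1.2, and the 19 remaining sets of the same genes had a median of 0.0174 (95% bootstrap interval -0.153 to 0.335), with 5 called higher and 1 lower. Those rises may belong to 1 probe set more than to the gene. The leading set was chosen as the largest, which favours a lower value in the others, and the sets of a gene can measure different transcripts.

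Another test compared genes that are neighbours on a chromosome. Where their probe set numbers lay within 5 of each other (6337 pairs) their log2 differences correlated at 0.163, and where the numbers lay over 200 apart (10637 pairs) at 0.02, a difference of 0.143 (95% bootstrap interval 0.11 to 0.177). Near pairs with different name stems gave 0.173. The same contrast was 0.128 against 0.037 for HpsPr-WC, and the control arrays' own deviations had near correlations of 0.0512 to 0.0985. The numbers do not run in a single series along a chromosome. STAC lies between NKIRAS1 and ACAA1, yet its set is TC0300007025.hg.1 and theirs are TC0300010515.hg.1 and TC0300010744.hg.1. Neighbours with far numbers may therefore come from different series, and what divides the series was not tested. The contrast cannot separate the numbering from that division, so no conclusion is drawn from it. Correlations of this size leave most of the variance elsewhere. How many calls depend on the numbering was not measured: the running median spans many more numbers than the near pairs.

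None of these tests speaks against a response of the cells to the hairpin. That response, which the design names, stays open, on its target or off it. The tests of the families and of the remaining probe sets show only that values needed by those technical explanations are there. The numbering test decides nothing. Carry-over of hairpin DNA into the labelled material might also raise or lower probe signal in these arrays (rises in the families above, ratio 1.12). Neither hairpin nor probe sequences were at hand to test it.

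The second pattern weighed is that BIRC5 was not lower in the arrays labelled HpsPr-WT. A probe set that fails to follow BIRC5 transcripts might explain it. Over the 9 arrays the deviation of BIRC5 from its group means and that of the mitosis list correlated at r 0.0247 (permutation p 0.949 over 216 orders; rho -0.133, p 0.722), and at 0.109 without the 2 arrays farthest from the median. The list's own members correlated with the rest at a median of 0.193 and only 2 of 34 above 0.7, so the test has no power to decide. An exchange of the HpsPr-WC and HpsPr-WT labels might explain it too. BIRC5 differed by -0.146 in HpsPr-WC against control, with an interval from -0.419 to 0.126 that holds both no change and a modest fall, so this cannot be told apart from correct labels on BIRC5 alone. A hairpin that left BIRC5 mRNA unaltered at 24 h stays open, as untested.

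The 6 arrays of each comparison can be split in 10 ways, too few for a share under 0.05. The real split gave 4805 calls for the arrays labelled HpsPr-WT against control, 1 for HpsPr-WC against control and 3746 between the hairpins, and the highest count among the other splits was 0 in each. In each comparison 1 of 10 splits, the real one, gave a count as large. Every other split mixed both groups on each side, so any true group difference entered its error. Counts of 0 there are therefore no support for the real split.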
